A study of Mus musculus with 12 samples.

How the data were processed

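Gene expression was measured with Visium, which captures polyadenylated RNA from a tissue section on an array of barcoded spots and counts transcripts by unique molecular identifiers (UMIs). Per the labels, 12 male C57BL/6J mice received 1 session of intermittent theta burst stimulation (iTBS), continuous theta burst stimulation (cTBS) or sham stimulation, 4 mice each. Each mouse gave 1 coronal section of the right hemisphere, 10 µm thick and 0.26 to 0.74 mm anterior of bregma, collected 3 hours after stimulation. The mouse is the replicate throughout, and a spot can hold several cells.

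The deposited matrices hold raw UMI counts for 32285 genes in every spot, which the authors made with Space Ranger and the mm10 genome build. Per the file headers, Cell Ranger 4 wrote 3 of these matrices (sham 1, sham 2 and iTBS 1) and Space Ranger 2.0.0 wrote the other 9. The deposited barcode, gene, position and image scale files are of other kinds and hold no expression values. The matrix of spots over tissue was checked to equal the same spots of the full matrix in all 12 sections. The image scale factor put sham 1, sham 2, iTBS 1 and iTBS 2 in imaging batch A, and sham 3, sham 4, iTBS 3 and iTBS 4 in batch B. All 4 cTBS sections were put in batch C because their position files alone have a header line. Their scale factors (0.1569 in each) are close to those of batch B (0.1571), while batch A has 0.1744 to 0.1785. Batch C thus rests on the file layout. These batches are inferred and not in the labels, and iTBS 2 has the software and the line ends of batch B. Batch and stimulation can therefore be separated for iTBS against sham, but not for cTBS.

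The comparisons, the regions and their markers, 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Spots over tissue with at least 250 UMIs were kept, which left 26332 spots. Counts were scaled to 10000 per spot and log-transformed. Genes of the activity lists, haemoglobins, ribosomal proteins and mitochondrial genes were left out, and each gene was centred and scaled within its section. The 2000 most variable genes seen in over 2% of spots gave 30 principal components. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) used 20 nearest neighbours from scikit-learn 1.9.0 and a resolution of 1.2. A cluster took a region's name when at least 3 of its fixed markers were among the 60 leading genes and more of them were in the top 10 than for any other region. Where fewer than 3 were in the top 10, no other region could have more among the 60. The fixed plan asked only for 3 detected markers, and this stricter rule was written after the clusters were seen. Clusters with the same name were merged. As an alternative, each spot took the region with the highest mean z-score of its markers.

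Raw counts were summed per section and region. The 9 regions tested had at least 20 spots in every section: layers 1, 2/3, 5 and 6, the cortex of all layers, white matter, caudoputamen, ventral striatum, and the olfactory cortex with endopiriform nucleus. Layer 4 had no spot in cTBS 4, and the ventricle lining had too few spots in some sections. No cluster took the name of the choroid plexus. Layer 4 in 11 sections, the septum and the preoptic area were tested as additions chosen after seeing the data.

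Each region was fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, with the 3 groups in 1 fit. Adjusted p is from the Benjamini-Hochberg method within a region and contrast, two-sided, with a threshold of 0.05. CPM is the value of edgeR's cpm with the TMM-scaled library size, and an error after ± is the SD of 4 sections (3 for cTBS in layer 4) unless SE is written. The difference of a contrast between cortex and caudoputamen, and between layers 2/3 and 6, was tested with the mouse as a block over 24 sums. Gene lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a region and contrast. A list needed 5 measured members. Camera with an estimated correlation stands beside it, and so does fry, which tests a list against no change and not against other genes. Ribosomal proteins (symbols starting with Rpl or Rps) brought the lists to 29. The blood list never had enough measured members, nor did the choroid plexus list, so neither was tested. The immediate early gene index is the mean log2 CPM (prior count 2) of the measured members of that list in a section. It was compared by an exact two-sided permutation test over 70 assignments, whose smallest possible p is 0.0286.

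The genes named were those of a fixed rule with 5 parts. Part 1 takes, in the cortex of all layers, up to 6 genes per direction with the smallest p among those past the threshold. Part 2 takes, in each region, up to 2 per direction with the largest fold among those past the threshold with a mean of at least 20 CPM. Part 3 takes, in a region with none past the threshold, 1 gene per direction with the smallest p, said not to have passed. Part 4 takes Fos, Egr1, Arc, Junb, Nr4a1, Npas4 and Bdnf in the cortex. Part 5 takes up to 3 members with the smallest p of each list that passed. Up to 3 genes per direction were taken from each test of a difference between regions. Predicted genes, pseudogenes and mitochondrial genes were counted but named only within lists. Genes named outside this rule are marked as chosen after their values were seen. Gene positions are from the GRCm38 annotation.

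The fit was tested on simulated data with the depth and spread of these sections, where 200 genes were changed by folds of 1.25, 1.5, 2 or 3. The simulated sections were drawn independently and without imaging batches. In the cortex the fit recovered 0% of genes changed 1.25-fold, 20% at 1.5, 62% at 2 and 88% at 3, and called 7 of 13075 unchanged genes. Fixed alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, only the 2 groups compared, the score-based regions, the replicate number as a block, counts thinned to the smallest section, and leaving out each section. Added after seeing the data were the imaging batch as a block, each batch alone, limma voom with the batch as a random effect, and camera without cTBS 4. Intervals of shares are 95% Wilson intervals and cover counting error only. Scripts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Protein, imaging and behavioural data were not used here. Some genes that the rule for named genes would include are not reported here.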

Results

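Visium sections of the right hemisphere were compared between mice given a single session of iTBS, cTBS or sham stimulation, with 4 mice per group and 1 section per mouse. Each section held the cortex, the corpus callosum and other white matter, the caudoputamen, the ventral striatum, the septum and part of the basal forebrain. Between 2053 and 2733 spots lay over tissue in a section. The UMI totals over tissue were 26707059, 21460366, 23441353 and 12930032 in sham 1 to 4, and 18462915, 23123987, 21700705 and 30723329 in iTBS 1 to 4. They were 20033088, 17790258, 16753128 and 8357945 in cTBS 1 to 4. The median UMI count per spot was 1613 in cTBS 4 and 5051 to 13342 in the other sections.

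Section cTBS 4 stood apart from the rest. Of its 2733 spots over tissue, 1194 held fewer than 250 UMIs and were left out, and its remaining cortex and caudoputamen were a medial and a ventral strip. Mitochondrial transcripts made 4.29% of its UMIs (4.28 to 4.31), against 10.5 to 14.9% in the other 11. UMIs outside tissue were 18.9% of all UMIs in cTBS 4 (18.92 to 18.96), 18.1% in sham 2 (18.09 to 18.12) and 16.5% in sham 1 (16.48 to 16.51). The other 9 sections had 3.01 to 8.84%. Counts of genes in the regions tested are therefore also given without cTBS 4, but not for the added septum and preoptic area.

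Clustering of 26332 spots gave 15 clusters, of which 13 were named from markers of regions. The layer 2/3 cluster was led by Vip, Lamp5 and Stard8, that of layer 5 by Fezf2, Myl4 and Dkkl1, and that of layer 6 by Ighm, Trbc2 and Myl4. Leading genes of white matter included the myelin genes Mbp and Mal, and layer 1 was led by the meningeal genes Mgp, Myoc and Ptgds. A cluster of 1945 spots led by Itih3, Agt and Slc6a11 and another of 334 spots led by Slc10a4, the choline transporter gene Slc5a7 and Slc17a8 stayed unnamed. The latter had 3 septum markers among its leading genes, but 12 of the caudoputamen. The ventral striatum cluster had 5 of its own markers there and 8 of another region, and was named by 3 in the top 10 against 2. Naming each spot by marker scores gave the same region for 59.6% of 24053 named spots, from 20% in the ventral striatum to 96.5% in white matter.

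**Figure D1:**
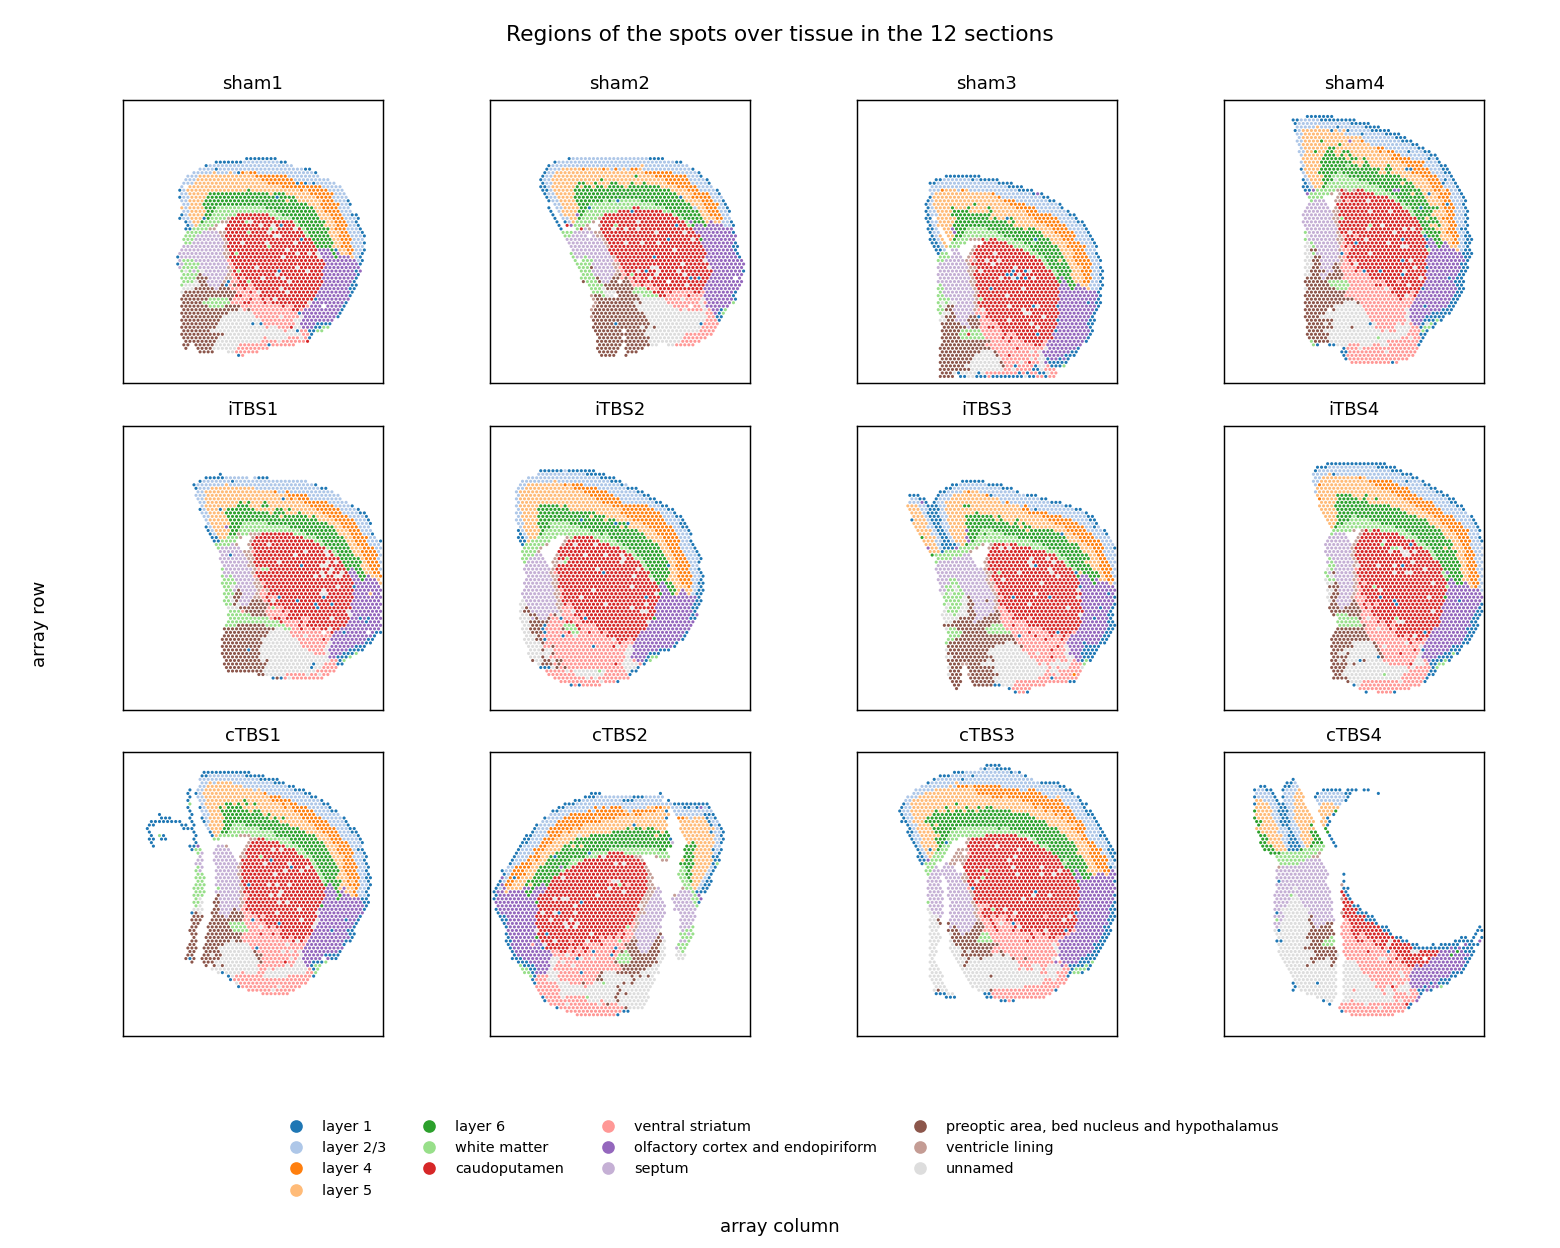
Each panel is 1 section, with the array column across and the array row down (in spots), and each point is a spot over tissue coloured by the region of its cluster. Cortical layers ran as bands around the caudoputamen in 11 sections, and cTBS 4 has no layer 4 spot.

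The comparison of iTBS with sham asks which transcripts of each layer and region differed 3 hours after an intermittent session. Mitochondrially encoded transcripts, which code for subunits of the respiratory chain, rose as a list in layer 5 (median log2 fold change 0.38, 12 of 13 higher, camera adjusted p = 1.12e-11) and in layer 6 (0.34). They also rose in the cortex of all layers (0.20), layer 2/3 (0.20) and the caudoputamen (0.18), with adjusted p = 0.590 to 0.96 with an estimated correlation in these 5 regions. In layer 6 mt-Nd1 was at 5385 ± 1055 CPM in iTBS and 3428 ± 584 in sham, and in layer 5 mt-Nd4l was at 387 ± 64.0 and 273 ± 66.5. Genes of striatal projection neurons fell in white matter (median −0.56, 11 of 11 lower, adjusted p = 1.20e-11), with adjusted p = 0.197 with an estimated correlation. Penk, the enkephalin precursor, was at 147 ± 43.3 CPM in iTBS white matter and 254 ± 31.5 in sham, and was lower in 4 of 4 sections than in every sham section.

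The same striatal list fell in layer 1 (median −0.29), layer 6 (−0.22), the olfactory cortex (−0.23) and the cortex (−0.15, 15 of 15 lower, adjusted p = 7.14e-07), with adjusted p = 0.590 to 0.743 with an estimated correlation. In the caudoputamen its median was −0.01 and it did not pass (camera adjusted p = 0.955). Tac1, the substance P precursor, was at 37.1 ± 5.54 CPM in the iTBS cortex and 52.6 ± 3.31 in sham, lower in 4 of 4 sections (log2 fold change −0.50, SE 0.11), and did not pass (edgeR adjusted p = 1). Adjusted over the list alone, 3 members fell in white matter and 1 each in layer 1 and the cortex, against 0 over all genes tested. The cortex median was −0.08 in imaging batch A and −0.30 in batch B. White matter had −0.56 and −0.45 in these batches, and the olfactory cortex −0.50 and 0.12.

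Layer 1, which also holds the meninges, had higher genes of meninges and fibroblasts (median 0.42, 14 of 14 higher, adjusted p = 2.97e-07), of endothelial and mural cells (0.25, 15 of 17) and of astrocytes (0.12, 20 of 20). Genes of myelin and oligodendrocytes fell there (−0.25, 20 of 23 lower, adjusted p = 3.48e-07). For these 4 lists adjusted p = 0.607 to 0.625 with an estimated correlation, and no member passed, over all genes or adjusted over the list alone. The layer 1 cluster was named by markers that include the meningeal genes Mgp and Ptgds, and 46.8% of its spots kept the name by marker scores. How much meninges or deeper tissue its spots held in each section was not measured, so these list calls cannot be told apart from it. Slc6a13, a GABA transporter of the meninges, was at 63.9 ± 22.0 CPM in iTBS and 33.9 ± 14.9 in sham, and Mbp, a myelin protein, at 987 ± 240 and 1390 ± 250. In layer 2/3 the microglial list rose (0.15, 16 of 16 higher, adjusted p = 0.000220), with Cx3cr1, the fractalkine receptor, at 19.5 ± 6.94 and 11.6 ± 4.27 CPM. The endothelial list rose too (0.20, 14 of 16), with Pecam1, an adhesion molecule of endothelium, at 10.2 ± 2.44 and 6.47 ± 0.629 CPM, while oligodendrocyte precursor genes (−0.21, 9 of 11 lower) and myelin genes (−0.09) fell. In layer 2/3 these 4 lists had adjusted p = 0.101 to 0.568 with an estimated correlation.

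In the caudoputamen the ependymal list, genes of the cells that line the ventricle beside it, rose (median 0.20, 6 of 8 higher, adjusted p = 0.000211). This was the only list call of the 3 comparisons to hold with an estimated correlation (adjusted p = 0.0336), and fry, a test against no change, gave 0.0116. Mia alone rose when adjusted over the list alone, at 5.20 ± 0.548 CPM against 2.89 ± 0.737, and none over all genes. Presynaptic (0.12), cytoskeletal (0.06) and microglial (0.09) lists also rose there, with adjusted p = 0.804 with an estimated correlation for each.

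In the ventral striatum and the olfactory cortex, postsynaptic genes rose (medians 0.09 and 0.12) and nuclear genes of oxidative phosphorylation (−0.10 in both) and of ribosomal proteins (−0.06 and −0.07) fell. These had adjusted p = 0.743 to 0.833 with an estimated correlation. Rpl35, a protein of the large ribosomal subunit, was at 498 ± 223 CPM in the iTBS ventral striatum and 897 ± 134 in sham. Presynaptic (0.08) and cytoskeletal genes (0.10) rose and immediate early genes fell (−0.14, 21 of 26 lower, adjusted p = 0.0281) in the ventral striatum, and microglial genes rose (0.14) in the olfactory cortex. They too had adjusted p = 0.743 to 0.833 with an estimated correlation. Coq10b, on the immediate early list, was at 23.3 ± 3.13 and 33.7 ± 5.69 CPM in the ventral striatum. The index of that list there was −0.13 in iTBS minus sham, but 0.013 without iTBS 3 and −0.0059 without sham 2. Oxidative phosphorylation genes also fell in layer 1 (−0.08) and myelin genes in layer 6 (−0.11), with adjusted p = 0.692 and 0.590 with an estimated correlation. In total 34 list calls passed for iTBS against sham, and 1 held with an estimated correlation. With the imaging batch as a block all but cytoskeletal genes in the ventral striatum (adjusted p = 0.0512) stayed under the threshold.

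No single gene passed for iTBS against sham in any of the 9 regions by the edgeR quasi-likelihood test, out of 7139 genes in white matter to 13433 in the cortex, and DESeq2 also called 0 in each. At an unadjusted p under 0.05 there were 183 genes in layer 1, 143 in layer 2/3, 122 in layer 5, 189 in layer 6 and 110 in the cortex. White matter had 158, the caudoputamen 136, the ventral striatum 202 and the olfactory cortex 197. Chance alone would give 357 in white matter to 672 in the cortex, more than were seen in each region. This fit has no term for the imaging batch, which iTBS and sham cross evenly. Differences between batches thus add to its spread and can make the test conservative. The genes of smallest p, none of which passed, were Vstm4 in the cortex (0.77), Zic1 (0.98) and Pcp4 (−0.74) in layer 1, Col11a2 (0.95) and Apoa1 (−1.70) in layer 2/3, and Trmu (0.74) and Gstp1 (−1.75) in layer 5. They were Col6a1 (0.80) and Coro1b (−2.75) in layer 6, Cib1 (0.79) and Gstp1 (−1.53) in white matter, and Mia (0.90) and Snhg1 (−0.64) in the caudoputamen. The ventral striatum had Bmt2 (0.70) and Coro1b (−2.54), and the olfactory cortex Prrc1 (1.01) and Gstp1 (−2.14, adjusted p = 0.587). Leaving out sham 4 gave 2 genes in layer 1 and the olfactory cortex and 1 in layers 2/3, 5 and 6, white matter and the ventral striatum. Leaving out sham 1 or sham 3 gave 1 in white matter, as did the batch as a block. Within batch A alone 1 to 22 genes passed per region, against 0 in batch B, with 2 sham and 2 iTBS sections in each. In batch A only the matrix of iTBS 2 was written by Space Ranger 2.0.0, and the software was not tested.

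**Figure D2:**
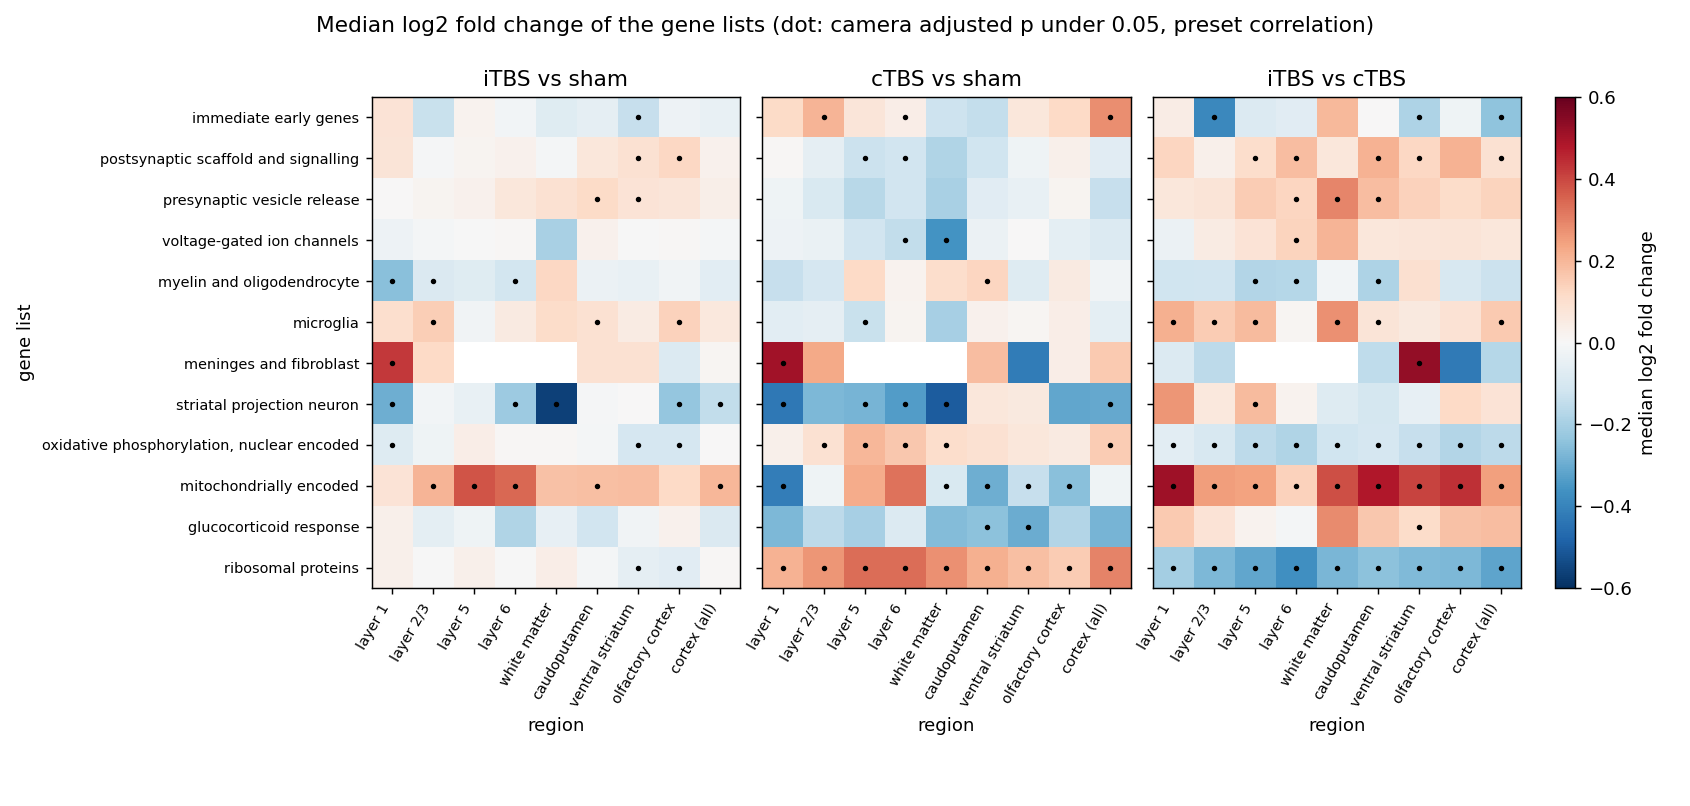
Colour gives the median log2 fold change of a gene list in a region for each of the 3 contrasts, with gene lists down and regions across, and a dot marks an adjusted p under 0.05 by camera at the preset correlation. Only lists with at least 3 such calls are drawn. White cells were not tested or had a median near 0. Ribosomal proteins were higher in cTBS than in sham in all 9 regions.

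Immediate early genes, which neurons switch on within minutes to hours of activity, were compared as an index and as single genes of the cortex. Fos was at 43.4 ± 13 CPM in iTBS, 43.0 ± 10.3 in cTBS and 38.4 ± 21.2 in sham. Egr1 was at 308 ± 46.4, 393 ± 63.9 and 290 ± 55.7 CPM in the same order, and its log2 fold change in cTBS was 0.44 (SE 0.16, edgeR adjusted p = 0.237). Arc, a regulator of synaptic receptors, was at 158 ± 40.5, 186 ± 34.2 and 174 ± 89.5 CPM. For iTBS against sham the log2 fold changes were −0.02 for Junb, −0.06 for Nr4a1, 0.27 for Npas4 and 0.11 for the growth factor Bdnf. For cTBS they were −0.23, −0.24, 0.33 and 0.05, and none of these genes passed.

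The index in the cortex was 4.76 ± 0.253 in iTBS, 4.95 ± 0.146 in cTBS and 4.75 ± 0.440 in sham. It differed from sham by 0.01 in iTBS (exact permutation p = 0.943) and by 0.20 in cTBS (exact p = 0.571). Without sham 4, whose index was the lowest, these differences were −0.20 and −0.01. Over 27 tests in 9 regions the smallest exact p was 0.0286, for iTBS against cTBS in layer 2/3 (−0.29, adjusted p = 0.771), and none passed. This is the smallest p that 70 assignments can give, so a single region at it could not pass among 27 tests. Within imaging batch A iTBS minus sham was −0.14 in the cortex, and within batch B it was 0.16.

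**Figure D3:**
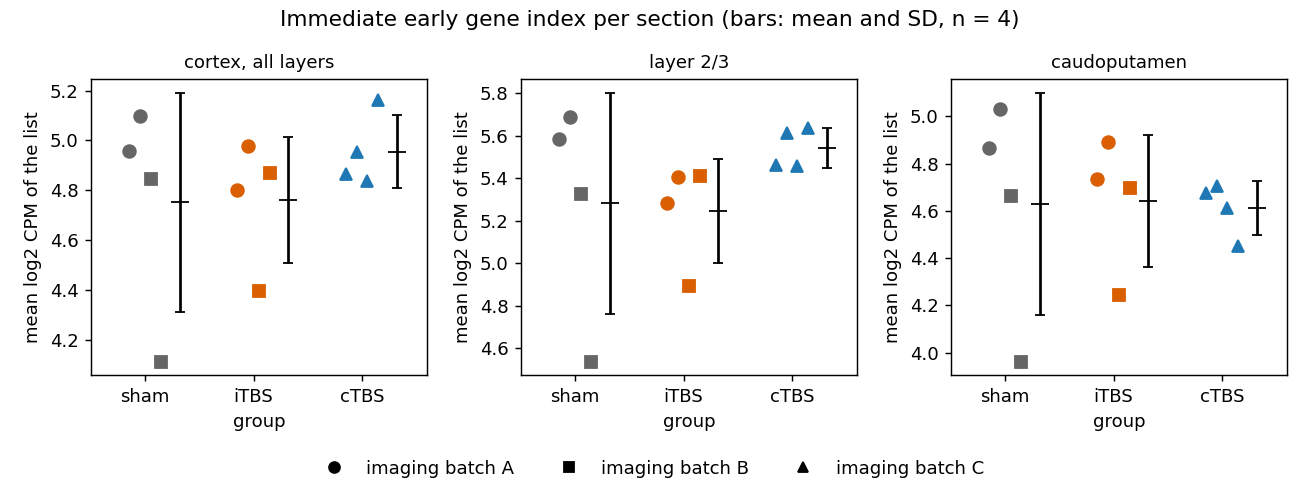
Points are sections, shaped by imaging batch, with the immediate early gene index (mean log2 CPM of the list) up and the group across in 3 regions, and bars are the mean and SD of 4 sections. In the cortex the group means were 4.75 in sham, 4.76 in iTBS and 4.95 in cTBS, and sham 4 was the lowest section.

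The comparison of cTBS with sham asks the same of a continuous session. In layer 6 Rps24, a protein of the small ribosomal subunit, rose to 2318 ± 89.3 CPM from 1327 ± 120 (log2 fold change 0.81, SE 0.13, adjusted p = 0.0322). Cntnap1, an axonal protein of the junctions beside the nodes of Ranvier, fell there to 56.3 ± 9.0 CPM from 110 ± 13.6 (−0.96, SE 0.15). Dmtn, an actin-bundling protein, fell to 125 ± 15.2 from 220 ± 32.6 (−0.83, SE 0.14). In the caudoputamen Plppr4, a postsynaptic protein that acts on glutamatergic transmission, fell to 68.8 ± 11 CPM from 149 ± 34.6 (−1.15, SE 0.17, adjusted p = 0.0359), and Rai1, a transcriptional regulator, to 24.1 ± 5.13 from 45.0 ± 7.26. In the olfactory cortex Slc4a10, a neuronal bicarbonate transporter, fell to 47.8 ± 9.21 CPM from 99.6 ± 15.0 (−1.04, SE 0.15, adjusted p = 0.0189). In white matter Ttr, the thyroid hormone carrier of the choroid plexus, passed (7.57, SE 1.23, adjusted p = 0.0170) on the values of cTBS 2 and 3, at 5148 and 8174 CPM, against 42.6 and 51.3 in cTBS 1 and 4 and 12.4 ± 20.4 in sham.

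The count was 3 genes in layer 6, 5 in the caudoputamen, all lower, and 1 each in white matter and the olfactory cortex, by edgeR. The other genes of the caudoputamen, chosen after their values were seen, were Rnf141 (21.0 ± 1.89 CPM from 37.0 ± 2.15), Mia2 (6.66 ± 2.15 from 16.8 ± 3.57) and Ccnb1 (0.337 ± 0.416 from 6.12 ± 3.33). No gene passed in layers 1, 2/3 and 5, the ventral striatum and the cortex. At an unadjusted p under 0.05 these had 870, 1328, 1570, 1211 and 2012 genes, and DESeq2 called 36, 62, 96, 17 and 212. In layer 6, the caudoputamen, white matter and the olfactory cortex DESeq2 called 105, 138, 9 and 34. Without cTBS 4 edgeR gave 0, 13, 2 and 8 in these 4 regions, 4 in layer 2/3, 29 in layer 5 and 16 in the cortex. Without sham 4 it gave 329, 760, 36 and 480 in the 4 regions, and without iTBS 3 it gave 134, 61, 11 and 59. Without sham 3 they were 21, 25, 13 and 3, and without sham 1, sham 2, cTBS 2 or cTBS 3 they were 0 in each. Without cTBS 1 they were 1 in each, and without iTBS 1, iTBS 2 or iTBS 4 the caudoputamen had 0 and white matter 8, 1 and 4, and iTBS 4 also gave 5 in layer 6. In layers 1, 2/3 and 5, the ventral striatum and the cortex it gave 87, 142, 226, 181 and 404 without sham 4, and in the 3 layers 16, 34 and 67 without iTBS 3 and 1, 4 and 6 without sham 3. In layer 5 it gave 8 without iTBS 1 and 1 without cTBS 1. By limma voom with the imaging batch as a random effect all 4 counts were 0, which changes the tool as well as the batch term. Since every cTBS section is in batch C the batch and cTBS cannot be told apart.

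Where none passed, the genes of smallest p were Rps24 (0.74, adjusted p = 0.115) and Cntnap1 (−0.74) in the cortex, Sulf2 (0.92) and Slc4a10 (−1.12) in layer 1, Rps24 (0.70) and Spink10 (−3.41) in layer 2/3, Rps24 (0.75) and Huwe1 (−1.13, adjusted p = 0.0504) in layer 5, and Myh7 (0.73) and Plppr4 (−0.87) in the ventral striatum.

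**Figure D4:**
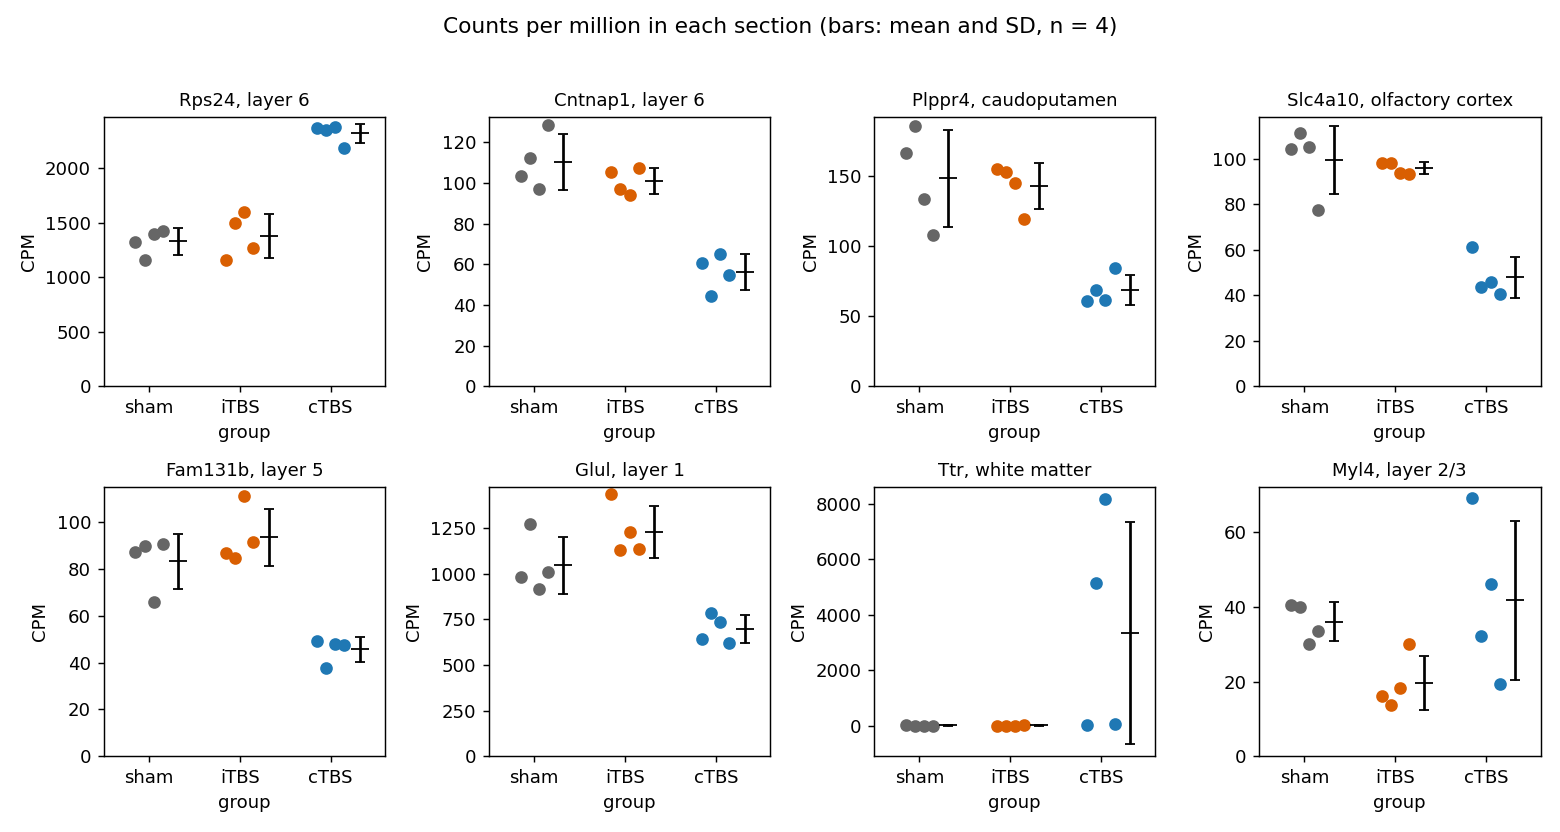
Points are sections, with CPM up from 0 and the group across for 8 genes in the region named, and bars are the mean and SD of 4 sections. Rps24 in layer 6 was 2318 CPM in cTBS against 1327 in sham, and Ttr in white matter was high in 2 of the 4 cTBS sections.

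Ribosomal protein genes rose as a list in cTBS against sham in all 9 regions, with medians of 0.30 in the cortex, 0.34 in layer 6, 0.33 in layer 5, 0.28 in white matter, 0.26 in layer 2/3 and 0.15 to 0.21 in the other 4. Over the 9 regions adjusted p = 0.447 to 0.928 with an estimated correlation. Without cTBS 4 they were higher, at 0.42, 0.46, 0.47, 0.45 and 0.36 in the same order, 0.38 in layer 1 and the caudoputamen, 0.34 in the ventral striatum and 0.31 in the olfactory cortex. In the cortex 67 of 79 were higher (adjusted p = 2.13e-14, and 0.628 with an estimated correlation). Adjusted over the list alone, 28 rose and 4 fell there, against 0 over all genes. In the cortex Rps24 was at 1999 ± 225 and 1197 ± 87.9 CPM, Rpl11 at 1265 ± 62.8 and 860 ± 42.2, and Rps28 at 288 ± 79.4 and 725 ± 292, the last below every sham section in 4 of 4. Rps24, Rps28 and Rpl11 have near-identical copies in the genome, which can take or give reads. Nuclear genes of oxidative phosphorylation rose in layers 2/3, 5 and 6, white matter and the cortex (medians 0.09, 0.20, 0.16, 0.11 and 0.15, and 0.14 in layer 2/3 without cTBS 4), with adjusted p = 0.512 to 0.875 with an estimated correlation. In the cortex 7 of 74 members rose adjusted over the list alone, and Ndufb8, a subunit of complex I, was at 726 ± 47.1 and 526 ± 20.8 CPM.

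Striatal projection neuron genes were lower in cTBS too, in the cortex (median −0.31, 15 of 15 lower, adjusted p = 3.29e-05), layer 1 (−0.43), layer 5 (−0.28), layer 6 (−0.34) and white matter (−0.50), with adjusted p = 0.406 to 0.826 with an estimated correlation. Adjusted over the list alone, 4 members fell in the cortex, among them Pde10a, a phosphodiesterase of the striatum, at 10.5 ± 3.8 against 28.4 ± 12.6 CPM. Mitochondrially encoded transcripts fell in layer 1 (−0.41, 13 of 13 lower, adjusted p = 3.39e-08), the caudoputamen (−0.29), the olfactory cortex (−0.25), the ventral striatum (−0.14) and white matter (−0.09), with adjusted p = 0.693 to 0.928 with an estimated correlation. In layer 1 mt-Nd4l was at 390 ± 110 and 839 ± 296 CPM, and 4 members fell adjusted over the list alone. Without cTBS 4 the call stayed in layer 1 alone (median −0.16, adjusted p = 0.00955), and the caudoputamen had a median of 0.05 (adjusted p = 0.836), the olfactory cortex 0.06 (0.801), the ventral striatum 0.16 (0.387) and white matter 0.22 (0.399).

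Immediate early genes rose as a list in the cortex (median 0.28, mean 0.11, 20 of 32 higher, adjusted p = 0.00476), in layer 2/3 (0.21) and in layer 6 (0.04), with adjusted p = 0.628 to 0.702 with an estimated correlation. Ier2, an early response gene, was at 49.7 ± 2.26 and 30.2 ± 8.72 CPM in the cortex and alone rose there adjusted over the list alone. Without cTBS 4 the cortex median was 0.18 and layer 6 did not pass (adjusted p = 0.0752). Without sham 4 the index of the list in cTBS minus sham was −0.013 in the cortex (from 0.20), 0.010 in layer 2/3 (from 0.26) and −0.071 in layer 6 (from 0.15). Postsynaptic genes fell in layers 5 and 6 (−0.13 and −0.12, adjusted p = 0.512 and 0.447 with an estimated correlation), and Camk2a, the kinase of the postsynaptic density, was at 388 ± 54.0 and 577 ± 58.1 CPM in layer 5. Genes of voltage-gated channels fell in layer 6 (−0.15) and white matter (−0.36), microglial genes in layer 5 (−0.14) and circadian clock genes in layer 5 (−0.33). These had adjusted p = 0.406 to 0.512 with an estimated correlation. In layer 5 the clock gene Npas2 was at 13.5 ± 4.10 and 23.6 ± 1.71 CPM.

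Glucocorticoid response genes fell in the caudoputamen (−0.24) and the ventral striatum (−0.30), with adjusted p = 0.928 and 0.569 with an estimated correlation. The hormone-induced factor Klf9 was at 88.5 ± 14.4 and 148 ± 38.5 CPM in the caudoputamen. Myelin genes rose in the caudoputamen (0.13, or 0.21 without cTBS 4, 3 of 24 adjusted over the list alone, adjusted p = 0.928 with an estimated correlation), where Opalin of oligodendrocytes was at 109 ± 22.9 and 71.4 ± 10.8 CPM. Meningeal genes rose in layer 1 (0.50, 3 of 14 adjusted over the list alone, adjusted p = 0.830 with an estimated correlation), with Slc6a13 at 80.9 ± 29.2 CPM. The amount of meninges in the layer 1 spots was not measured for cTBS either. Without cTBS 4 the glucocorticoid list did not pass (adjusted p = 0.0934 and 0.120), nor did microglia in layer 5 (0.0654), postsynaptic genes in layer 6 (0.0812), striatal genes in layer 6 (0.0752) or channels in layer 6 (0.134) and white matter (0.200). In total 37 list calls passed for cTBS against sham, and 0 held with an estimated correlation.

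The comparison of iTBS with cTBS asks whether the protocols differed from each other. In layer 6 Camk2a (479 ± 51.6 against 307 ± 30.4 CPM, log2 fold change 0.63, SE 0.13, adjusted p = 0.0483) was higher in iTBS. Rps24 (−0.75), Rpl11 (−0.62) and Opalin (−0.68, 85.8 ± 4.97 against 136 ± 20.9 CPM) were lower. Plppr4 was higher in iTBS in the ventral striatum (153 ± 13.9 against 68.6 ± 6.44 CPM, 1.15, SE 0.14, adjusted p = 0.00177) and in the olfactory cortex (121 ± 14.2 against 52.9 ± 9.61). Fam131b was higher in layer 5 (93.7 ± 12.2 against 45.7 ± 5.25 CPM, adjusted p = 0.0183) and in the caudoputamen (71.8 ± 10.0 against 34.0 ± 2.92). In layer 1 Glul, the glutamine synthetase of astrocytes, was at 1231 ± 143 against 696 ± 76.4 CPM (0.82, SE 0.14, adjusted p = 0.0400) and Agap2, a GTPase-activating protein, at 145 ± 70.2 against 37.4 ± 7.23. Huwe1, a ubiquitin ligase, was at 115 ± 21.4 against 48.9 ± 10.9 CPM in the olfactory cortex.

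The counts by edgeR were 28 in layer 6 (23 higher in iTBS), 6 in the olfactory cortex, 4 in layer 1, 3 in white matter and 1 each in layer 5, the caudoputamen and the ventral striatum. Dmtn and Cntnap1, chosen after their values were seen, were also among the 28 (log2 fold changes 0.94 and 0.84). Bc1, a noncoding RNA of neuronal dendrites (5.40 in layer 6, 5.95 in white matter), and Snhg9, a small nucleolar RNA host gene (3.72 and 3.24), were higher in iTBS. Both differed between imaging batches B and A within the sham and iTBS cortex (Bc1 −3.16, Snhg9 −1.80), as did Agap2 (−0.74). Lower in batch B without passing were Plppr4 (−0.43), Slc4a10 (−0.33), Glul (−0.30), Huwe1 (−0.28) and Dmtn (−0.27), with edgeR adjusted p = 0.0534 to 0.163. Rps24 was higher there (0.18, adjusted p = 0.247), and Cntnap1 (0.05) and Fam131b (0.08) had adjusted p = 0.776 and 0.741. Ttr in white matter was lower in iTBS (−8.26, adjusted p = 0.00707). In layer 2/3 and the cortex 0 genes passed, with 1116 and 1760 at an unadjusted p under 0.05 and 60 and 224 by DESeq2. Agap2 (1.75) and Rps24 (−0.67) in layer 2/3 and Fam131b (1.01) in the cortex were among the genes of smallest p there and did not pass. DESeq2 called 94, 119, 64, 3, 83, 131 and 41 in the 7 regions with calls, in the order given.

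Without cTBS 4 the counts in this order were 13, 12, 0, 9, 15, 13 and 1, with 4 in layer 2/3 and 23 in the cortex. Without iTBS 3 they were 251, 162, 69, 41, 124, 181 and 1, without sham 4 72, 23, 35, 17, 55, 84 and 1, and without iTBS 4 50, 26, 17, 16, 10, 26 and 5. Without sham 2 they were 40, 14, 21, 11, 6, 28 and 3, without sham 3 23, 7, 8, 3, 5, 11 and 1, and without sham 1 20, 5, 5, 7, 1, 1 and 1. Without cTBS 3 they were 0, 0, 0, 1, 0, 0 and 1, without cTBS 2 1, 0, 0, 5, 0, 0 and 1, and without cTBS 1 1, 4, 0, 1, 1, 1 and 1. Without iTBS 1 they were 0, 1, 0, 0, 1, 0 and 1, and without iTBS 2 17, 2, 0, 3, 1, 1 and 1. In layer 2/3 there were 57 without iTBS 3, 35 without sham 4, 13 without iTBS 4, 10 without sham 2 and 4 without sham 3, and in the cortex 31 without sham 4 and 1 without iTBS 4. By limma voom with the imaging batch as a random effect the ventral striatum had a count of 1 and the other 6 had 0.

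Ribosomal protein genes were lower in iTBS than in cTBS in all 9 regions, with medians of −0.37 in layer 6 and −0.32 in the cortex (68 of 79 lower, adjusted p = 1.33e-15), and oxidative phosphorylation genes were lower in all 9 (−0.16 in the cortex). For both lists adjusted p = 0.520 to 0.887 with an estimated correlation. Adjusted over the list alone, 40 ribosomal genes fell and 4 rose in layer 6, against 2 over all genes. Mitochondrially encoded transcripts rose in all 9 regions (0.51 in layer 1, 0.48 in the caudoputamen, 0.24 in the cortex), with adjusted p = 0.516 to 0.827 with an estimated correlation. Without cTBS 4 this passed in layer 1 (adjusted p = 0.000172), and the cortex had a median of 0.02 (0.357). Layer 5 and layer 6 had −0.01 and −0.08 without it.

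Postsynaptic genes rose in layers 5 (0.11) and 6 (0.18), the caudoputamen (0.21), the ventral striatum (0.12) and the cortex (0.09), with adjusted p = 0.353 to 0.823 with an estimated correlation. Presynaptic genes rose in layer 6 (0.13), white matter (0.29) and the caudoputamen (0.18), and glutamate receptor (0.23) and channel genes (0.13) in layer 6. For these adjusted p = 0.28 to 0.823 with an estimated correlation. Microglial genes rose in the cortex (0.16), layers 1, 2/3 and 5, white matter (0.27) and the caudoputamen, with adjusted p = 0.588 to 0.823 with an estimated correlation. Selplg was at 24.7 ± 4.42 against 14.6 ± 3.33 CPM in the cortex.

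In iTBS against cTBS immediate early genes fell in layer 2/3 (−0.39, 21 of 29 lower, 5 of them adjusted over the list alone, adjusted p = 1.36e-05), the cortex (−0.24) and the ventral striatum (−0.18), with adjusted p = 0.634 to 0.806 with an estimated correlation. Gadd45g of that list was at 28.5 ± 1.77 against 51.7 ± 20.2 CPM in layer 2/3. Without iTBS 3 the difference of the index was −0.18 in layer 2/3 (from −0.29), −0.071 in the cortex (from −0.19) and −0.045 in the ventral striatum (from −0.19). Myelin genes fell in layers 5 and 6 (−0.17 in both) and the caudoputamen (−0.19), with adjusted p = 0.525 to 0.823 with an estimated correlation. Striatal genes rose in layer 5 (0.19), and astrocyte (0.17), meningeal (0.53) and glucocorticoid genes (0.11) in the ventral striatum. These lists had adjusted p = 0.650 to 0.806 with an estimated correlation, and of all 53 list calls 0 held. Without cTBS 4 the astrocyte (0.152), meningeal (0.0576), glucocorticoid (0.185), channel (0.0590) and striatal lists (0.111) did not pass. Microglia in layers 1 (0.133) and 2/3 (0.0698) and the caudoputamen (0.271) and presynaptic genes in layer 6 (0.131) and the caudoputamen (0.159) did not pass without it either. Among lists that passed without it, the median was 0.18 for presynaptic genes in white matter, 0.20 for postsynaptic genes in the ventral striatum and −0.26 for myelin genes in layer 5.

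Over the 3 comparisons the other 8 tested lists never passed. Their smallest camera adjusted p were 0.0517 for heat shock genes, 0.0610 for cortical excitatory neurons, 0.0741 for GABA signalling, 0.0903 for delayed activity-regulated genes, 0.152 for inflammation, 0.158 for cortical interneurons, 0.173 for neurotrophin signalling and 0.198 for calcium handling.

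Whether an effect differed between regions was tested directly with the mouse as a block. Myl4, a myosin light chain and a leading gene of the layer 5 and 6 clusters, differed between layers in iTBS (difference of log2 fold changes −1.27, SE 0.19, adjusted p = 1.6e-05). It was at 19.5 ± 7.22 CPM in iTBS layer 2/3 against 36.1 ± 5.17 in sham, and at 303 ± 52.4 against 247 ± 60.6 in layer 6. In cTBS Nefm, a neurofilament protein of large axons, differed by 0.48 (SE 0.10, adjusted p = 0.0319), at 287 ± 101 against 185 ± 30.8 CPM in layer 2/3 and 203 ± 58.3 against 179 ± 18 in layer 6. Ptgds, a prostaglandin synthase and a leading gene of layer 1, differed by −0.41, at 367 ± 40.0 against 450 ± 101 CPM in layer 2/3 and 618 ± 143 against 599 ± 83.6 in layer 6. The count between layers 2/3 and 6 was 2 for iTBS, Myl4 and the predicted gene Gm42418 (chosen after its values were seen, 0.81), and 6 for cTBS, with 4 mitochondrial transcripts. For iTBS it was 7 without sham 1 or sham 3, 5 without iTBS 4 and 4 without iTBS 3, and 3 without cTBS 4. For cTBS it was 11 without sham 1, 6 without cTBS 3, 2 without cTBS 1, cTBS 4 or sham 4, and 0 without any other section. Between the cortex and the caudoputamen 0 genes passed by edgeR for either protocol, with 470 and 790 at an unadjusted p under 0.05 and 686 given by chance. The genes of smallest p there were Snhg1 (0.38) and Scrt2 (−0.50) for iTBS and Id2 (0.58) and Apod (−0.36) for cTBS. Without iTBS 3 iTBS gave 3 there, and without cTBS 1 cTBS gave 1.

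Log2 fold changes of iTBS and of cTBS against sham correlated across genes with r of 0.29 in the cortex and 0.32 to 0.37 in the other 8 regions. Both share the 4 sham sections, and simulated unchanged groups that share them gave 0.49 ± 0.02 in the cortex (SD of 20 simulations). The simulations held no imaging batches, which sham and iTBS share and cTBS does not, so the observed r cannot be judged by them. With the sham sections shared out between the protocols, so that neither used the same ones, r in the cortex was −0.26, −0.14 and −0.08 in the 3 ways of sharing. The first way set the sham sections of batch A against those of batch B, and the other ways did not, with r also below 0. Unchanged groups were not simulated for shared-out sham sections, so a negative r does not show opposed effects of the protocols. Genes are not independent replicates, so no p is given.

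Some of the genes past the threshold lie, in GRCm38, at chromosome 14 from 24490678 to 24496960 (Rps24), chromosome 11 from 101174617 to 101190724 (Cntnap1), chromosome 14 from 70602184 to 70636048 (Dmtn) and chromosome 3 from 117319145 to 117360876 (Plppr4). Slc4a10 lies at chromosome 2 from 62046472 to 62326743, Fam131b at chromosome 6 from 42315305 to 42324640, Glul at chromosome 1 from 153899929 to 153909723 and Ttr at chromosome 18 from 20664209 to 20674326.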

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

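The test of the immediate early gene index without sham 4, the fits with imaging batch as a block or a random effect, the values within each batch and the use of layer 1 and of single sections to judge the patterns, and the splits with batches balanced were chosen after the results were seen. A section far from the other 3 of its group was looked for in 270 sets of values. It was found in 20, where chance marks about 1 in 20 groups, or 13.5. The immediate early gene index of sham 4 lay far below the other sham sections in layer 1 (4.81 against 5.47 to 5.59), layer 6 (4.58 against 5.38 to 5.53) and white matter (4.81 against 5.38 to 5.47). That of iTBS 3 was low in layer 1 (5.09 against 5.53 to 5.59).

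Section cTBS 4 was far from the other cTBS sections for Rps24 in the cortex (1663 CPM, lowest) and layer 6 (2185, lowest). It was so too for Bc1 (12.9, lowest), Snhg9 (22.6, highest) and Myl4 (181, lowest) in layer 6. Slc6a13 of the meninges in layer 1 was high in cTBS 3 (124 CPM), and Fam131b in layer 5 was low in cTBS 2 (37.9) and in sham 3 (66.0). Mbp in layer 1 (630.2 CPM) and Camk2a in layer 6 (402 CPM) were low in iTBS 2. In iTBS 1 mt-Nd4l was high in layer 5 (482 CPM) and Ptgds low in layer 6 (458 CPM), and in iTBS 4 Plppr4 was low in the ventral striatum (132 CPM). Ttr in white matter was high in sham 1 (43.0 CPM against at most 3.70 in the other 3 sham sections). Rai1 in the caudoputamen was high in sham 2 (55.8 CPM), and Rnf141 in the olfactory cortex was low in sham 4 (35.7 CPM).

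Spots outside the tissue, which no comparison uses, held 18.9% of the UMIs of cTBS 4, above the highest sham section (18.1%). The effect of stimulation differed between layers 2/3 and 6, by a direct test, for Myl4 (−1.28) and Gm42418 (0.81) in iTBS. In cTBS it did so for Nefm (0.48), Ptgds (−0.41), mt-Co2 (−0.37), mt-Co3 (−0.34), mt-Nd4 (−0.35) and mt-Cytb (−0.34). With regions named by marker scores, which redraws the layers, 4 genes passed in iTBS, with 2 shared, and 1 in cTBS, with 1 shared. Chance was not excluded for these counts: 2 in iTBS, with 4 in the highest other split and 11 of 35 splits as large (6 of the 18 with batches balanced, the highest 4), and 6 in cTBS, with 12 and 2 of 35. For the cortex against the caudoputamen the real counts of 0 by edgeR (470 and 790 genes at an unadjusted p under 0.05, no other tool run) stood beside 6 and 2 in the highest other split. Any split gives at least 0, so for a count of 0, here and below, the splits say nothing about chance.

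For iTBS against sham, edgeR called 0 genes in each of the 9 regions (110 to 202 at an unadjusted p under 0.05, and 0 by DESeq2). With a count of 0 all 35 splits of the 8 sections into 4 and 4 gave as many by construction. The highest was in each region the split of imaging batch A from batch B. It gave 2747 genes in the cortex, 322 in layer 1, 1424 in layer 2/3, 1426 in layer 5, 1291 in layer 6, 290 in white matter, 1276 in the caudoputamen, 596 in the ventral striatum and 456 in the olfactory cortex. Such counts point to a structure of the samples, the batch, that the comparison of iTBS with sham crosses evenly. With the batch as a block iTBS against sham gave 1 gene in white matter and 0 in the other 8 regions by edgeR. For the 34 list calls, 30 of 35 splits gave as many, the highest 96, so chance was not excluded, and the batch split gave 30. These calls were at the preset correlation, and no split was run with an estimated one. Of the 18 splits that keep 2 sections of each batch in each group, as the real one does, 17 gave as many, the highest 96, and 0 to 2 genes passed per region in the other 17 by edgeR.

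For cTBS against sham chance was not excluded in the 4 regions with calls. In layer 6 (3 genes), the caudoputamen (5) and the olfactory cortex (1), 2 of 35 splits gave as many, with 408, 959 and 282 genes in the highest other split. In white matter (1) 5 of 35 did, with 61. The counts of 0 by edgeR were in layers 1, 2/3 and 5, the ventral striatum and the cortex. They stood beside 66, 44, 180, 169 and 234, with 870 to 2012 genes at an unadjusted p under 0.05 and 17 to 212 by DESeq2. The highest other split set sham 1 to 3 and cTBS 4 against sham 4 and cTBS 1 to 3, and its many genes point to a structure of the samples in which sham 4 goes with cTBS 1 to 3 and cTBS 4 with sham 1 to 3. Deviations of sham 4 from its group's mean in the cortex correlated by 0.42 with those of cTBS 3, 0.70 with iTBS 3 and −0.17 with cTBS 4, over genes that are not independent replicates. For the 37 list calls, 26 of 35 splits gave as many, with a highest of 78, so chance was not excluded.

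For iTBS against cTBS chance was not excluded in the 7 regions with calls. In layer 6 (28 genes), the olfactory cortex (6), layer 1 (4) and the ventral striatum (1), 2 of 35 splits gave as many, with 371, 244, 47 and 194 in the highest other split. In white matter (3), layer 5 (1) and the caudoputamen (1) 3 of 35 did, with 146, 308 and 639. Layer 2/3 and the cortex had 0 by edgeR (1116 and 1760 at an unadjusted p under 0.05, 60 and 224 by DESeq2), beside 168 and 446. The highest other split set iTBS 1, 2 and 4 and cTBS 4 against iTBS 3 and cTBS 1 to 3, which again points to a structure of the samples, in which iTBS 3 goes with cTBS 1 to 3. For the 53 list calls, 13 of 35 splits gave as many, with a highest of 93, so chance was not excluded.

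Ribosomal protein genes were higher in cTBS than in sham over the cortex (median log2 fold change 0.30). With every section thinned to the same total the median was 0.31. Thinning keeps each gene's expected share, so it cannot show whether shallow sections captured transcripts differently, and lower depth stays open. The tables argue against cTBS 4, since the median was 0.42 without that section. A difference between imaging batches may explain the pattern and stays open, because within the iTBS sections batch B was above batch A by 0.18, although within the sham sections by only 0.04. All cTBS sections are in batch C, so this and an effect of cTBS, which was not tested apart from the batch, cannot be told apart.

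Genes of striatal projection neurons were lower in iTBS than in sham outside the striatum (median −0.15 in the cortex, −0.56 in white matter). Spread of striatal transcripts over the section, more of which would be found in batch A where the sham sections have 16.5 and 18.1% of UMIs outside tissue, would make the difference larger in batch A. It stays open: the median was −0.56 in batch A and −0.45 in batch B in white matter, −0.50 and 0.12 in the olfactory cortex, but −0.08 and −0.30 in the cortex, where batch B rests on iTBS 3. Striatal tissue under spots at the border of white matter could give the pattern and stays open too, since the median was −0.017 in layer 2/3 but −0.29 in layer 1, where the iTBS and sham sections overlap. An effect of iTBS on striatal transcripts in these regions stays open as untested.

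The immediate early gene index of the cortex was lower in imaging batch B than in batch A (−0.40, exact permutation p = 0.0857), over the sham and iTBS sections. Fos (log2 difference −0.91), Junb (−1.04) and Npas4 (−1.05), 3 early genes of neuronal activity, were lower in batch B, and of the other 4 genes of activity Nr4a1 (−1.01), Arc (−0.66), Bdnf (−0.14) and Egr1 (−0.08) did not pass. The difference was −0.40 with every section thinned to the same total. Thinning keeps each gene's expected share, so it cannot show whether shallow sections lost these transcripts, and depth stays open. Whether single sections make the cortex difference stays open: it was −0.25 without sham 4, but then sham 3 and iTBS 4 lie within the range of batch A, and the rest is iTBS 3. In layer 1, white matter and the caudoputamen every batch B section lay below every batch A section (exact permutation p = 0.0286 in each, adjusted p = 0.0857). Without sham 4 the difference was −0.22 to −0.35 over the 9 regions. What differed between the batches, such as the time or the handling of the mice, is not in the labels and stays open, and an activity difference could not be tested apart from it.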

How the results depend on the processing

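The tests with imaging batch as a block or as a random effect and within a batch, the lists without cTBS 4, and layer 4 in 11 sections were chosen after seeing the data. Of the 41 results that answer a comparison, 370 values under the alternatives stayed the same and 291 moved. A count stayed the same if it was equal or within 1.5 times, and any change from or to 0 was a move. The immediate early gene index stayed the same if its difference kept its sign. The correlation of fold changes did so if it moved by no more than the SD of its simulations. Of 469 other results, mostly single genes, 8156 values were the same, 708 were past the threshold where the reported value was not, 180 were no longer past it, 119 moved and 0 changed direction past the threshold. In the lists below the order of regions is layers 1, 2/3, 5 and 6, white matter, caudoputamen, ventral striatum, olfactory cortex and cortex. Where a value moved, the cause was not tested unless it is given.

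Reported counts were 0 in each region for iTBS against sham, with 110 to 202 genes at an unadjusted p under 0.05 by edgeR and 0 by DESeq2. For cTBS against sham they were 0, 0, 0, 3, 1, 5, 0, 1 and 0, and for iTBS against cTBS 4, 0, 1, 28, 3, 1, 1, 6 and 0. DESeq2 gave 36, 62, 96, 105, 9, 138, 17, 34 and 212 for cTBS against sham and 64, 60, 83, 94, 3, 131, 41, 119 and 224 for iTBS against cTBS. RLE scaling gave 9 in layer 5 for cTBS against sham, and the other counts stayed within 1.5 times.

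With no filter on low counts, where more genes are tested, iTBS against sham gave 17, 3, 4, 13, 12, 2, 4 and 10 in the first 8 regions. In that setting cTBS against sham gave 219, 222, 315, 439, 138, 177, 163, 435 and 22, and iTBS against cTBS 197, 156, 239, 357, 122, 159, 205, 311 and 66. The interactions gave 5 and 20 for the cortex against the caudoputamen in iTBS and cTBS, and 8 and 13 for layer 2/3 against layer 6. With only the 2 groups compared in the fit, cTBS against sham gave 18 in layer 5, 69 in layer 6, 12 in white matter, 0 in the caudoputamen and 10 in the olfactory cortex, and iTBS against cTBS 24, 34, 50, 90, 18, 92, 8, 30 and 56.

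With regions named by marker scores, cTBS against sham gave 6 in layer 5, 5 in layer 6, 0 in white matter, 1 in the caudoputamen, 24 in the ventral striatum and 8 in the olfactory cortex. For iTBS against cTBS these regions gave 10, 6, 2, 7 and 0 in the first 5, 4 in the ventral striatum, 30 in the olfactory cortex and 19 in the cortex. Layer 4 had 0 for cTBS against sham, against 22 in clusters, and 13 for iTBS against cTBS, against 36, and its other alternatives were not run because it was absent from cTBS 4. Layer 2/3 against layer 6 gave 4 in iTBS and 1 in cTBS. With every section thinned to the smallest, cTBS against sham gave 7 in layer 1 and 0 in white matter and the olfactory cortex. Thinning gave 16 in layer 1, 3 in layer 5, 15 in layer 6, 5 in the caudoputamen and 2 in the ventral striatum for iTBS against cTBS.

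In the cortex, deviations of each section from its group's mean were correlated across genes between sections with the same replicate number. The values were 0.00 to 0.47 between sham and iTBS, and −0.17 to 0.15 between sham and cTBS. Between iTBS and cTBS they were −0.11 to 0.46. A section with another number correlated better, except for sham 1 with cTBS 1 and iTBS 3 with cTBS 3. Whether the numbers pair the mice is not in the labels, and these values, which also hold the imaging batch, cannot decide it. With the number as a replicate block iTBS against sham gave 1 in white matter. In that fit cTBS against sham gave 35, 92, 79, 242, 62, 273, 7, 192 and 23, and iTBS against cTBS 52, 85, 86, 211, 61, 202, 23, 146 and 78. Numbers 1 and 2 of sham and iTBS lie in imaging batch A and 3 and 4 in batch B, so this block also takes up part of the batch.

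With the imaging batch as a block iTBS against sham gave 1 in white matter. Within batch A alone it gave 13, 5, 4, 8, 1, 6, 4, 22 and 3, and within batch B 0 in each by edgeR. Each of these fits within a batch held 2 sham and 2 iTBS sections. By limma voom with the batch as a random effect, which changes the tool too, cTBS against sham gave 0 in layer 6, white matter, the caudoputamen and the olfactory cortex. In the same fit iTBS against cTBS gave 0 in layers 1, 5 and 6, white matter, the caudoputamen and the olfactory cortex. The gene lists, 34, 37 and 53 calls at the preset correlation, were 1, 0 and 0 with an estimated correlation and 1, 0 and 1 by fry, and 39, 42 and 41 without cTBS 4.

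Leaving out each section in turn gave, for iTBS against sham, 0 to 2 in layer 1 and the olfactory cortex, 0 to 1 in layers 2/3, 5 and 6, white matter and the ventral striatum, and 0 in the caudoputamen and the cortex. For cTBS against sham the ranges were 0 to 87, 0 to 142, 0 to 226, 0 to 329, 0 to 36, 0 to 760, 0 to 181, 0 to 480 and 0 to 404, each highest without sham 4. For iTBS against cTBS they were 0 to 69, 0 to 57, 0 to 124, 0 to 251, 0 to 41, 0 to 181, 1 to 5, 0 to 162 and 0 to 31. These were highest without iTBS 3, except in the ventral striatum (iTBS 4) and the cortex (sham 4). Interactions ranged 0 to 3 and 0 to 1 for the cortex against the caudoputamen in iTBS and cTBS, and 2 to 7 and 0 to 11 for layer 2/3 against layer 6. The immediate early gene index of the cortex ranged from −0.20 to 0.13 for iTBS against sham and −0.013 to 0.32 for cTBS against sham, and with total-count scaling iTBS against sham was −0.014, against 0.0089. The correlation of the fold changes in the cortex, 0.29, was −0.26, −0.14 and −0.078 when the protocols shared no sham section, which removes by construction what shared sections add. Why it went below 0 was not tested, and the first way, at −0.26, splits the sham sections by imaging batch.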

Other observations

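The tests in layer 4, the septum, the preoptic area and between imaging batches were chosen after seeing the data, with the same fit as in the other regions. In layer 4 (11 sections, none from cTBS 4), Phpt1, a phosphohistidine phosphatase, was at 39.9 ± 3.36 CPM in the 3 cTBS sections and 105 ± 19.1 in sham (log2 fold change −1.37). Kif3c, a kinesin motor of neurons, was at 53.3 ± 8.02 and 119 ± 19.8 (−1.13), and Rps24 (0.71) and the beta globin Hbb-bt (2.76) were higher in cTBS. In all 22 of 9072 genes passed there for cTBS against sham, 3 higher and 19 lower, and 36 for iTBS against cTBS, with Huwe1 at 117 ± 22.4 and 46.8 ± 1.76 CPM. With regions named by marker scores and all 12 sections these counts were 0 and 13 by edgeR. For iTBS against sham edgeR called 0, with 164 at an unadjusted p under 0.05, and DESeq2 was not run.

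In the septum Myh7, a myosin heavy chain, was at 125 ± 14.5 CPM in cTBS and 66.3 ± 15.4 in sham (0.94). It was the 1 higher gene of 10 that passed, and the other 9 were lower in cTBS. Plppr4 was at 123 ± 19.7 in iTBS and 52.4 ± 6.59 in cTBS (1.22) and was among 5 that passed. In the preoptic area Rps28, which has near-identical copies in the genome, was the 1 gene that passed for cTBS against sham (403 ± 82.3 and 1061 ± 334 CPM, −1.39, adjusted p = 0.0142) and for iTBS against cTBS (1.40, adjusted p = 0.0137). For iTBS against sham edgeR called 0 in the septum and the preoptic area, with 243 and 152 genes at an unadjusted p under 0.05, and DESeq2 was not run there. Fits of these 2 areas without cTBS 4 were not run either.

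In the sham and iTBS sections 1799 of 13598 cortex genes differed between imaging batches B and A, 863 higher and 936 lower in B. The counts were 198 in the olfactory cortex to 962 in layer 5 in the other 8 regions. Fold changes of batch B against A within iTBS correlated across genes with those of cTBS against sham, with r of 0.624 in the cortex and 0.438 to 0.618 in the other 8 regions. Genes are not independent replicates, so no p is given.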
